A study of Mus musculus with 5 samples.

How the data were processed

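RNA was sequenced from the total dorsal epidermis of C57BL/6 male mice at postnatal day 49, and 5 libraries were used here. Per the labels' protocols, the epidermis was taken from whole skin by dissection and trypsin overnight, RNA was extracted with Trizol and a column kit, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, bcl2fastq 2.17, STAR and Partek were used. The order and settings of these tools, the genome build and the gene annotation were not given in the sources used here.

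The deposited table listed 59869 transcripts in CPM (reads scaled to the library's total), a unit read from the values: the columns summed to between 805255.8 and 947144.3. In place of 0 the deposited CPM columns held a small offset of between 1.93527e-06 and 2.92585e-06. If that offset stood for 0.0001 read, the libraries held 49400000 reads (control), 48500000 and 50800000 (forskolin 1 and 2) and 51700000 and 34200000 (cAMP 1 and 2). On that scale, 59.5% to 76.3% of gene sums between 0.5 and 20 reads lay within 0.1 of a whole number, where chance gives 20%. Most of these sums were thus near whole, but the rest were not. Whole reads were therefore not recovered for the full set of genes, and no count model was run. The floor of 3 reads came to 0.0607 CPM in the control library and was divided by that library's size factor where values were rescaled. It covers counting error only, since no molecular identifiers were used.

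The table's columns carried library codes that matched the sample descriptions by their prefix and number, and this match was used to place each column in its group. Transcript values were summed per Ensembl gene, which gave 21667 genes; the planned test had assumed a table of genes. The 3 rows with no gene identifier held at most 0.0679% of a library and were left out of the tests. Start positions in the table were 1-based and stop positions 1 past the end. The coordinates were compared with GENCODE M21 on GRCm38: 98.3% of the transcripts were in that annotation, and 90.8% of those had the same start and end. Coordinates are given as in the table, with the end corrected by that base.

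Genes with at least 1 CPM in at least 2 libraries were tested, 13764 in all. limma 3.58.1 in R 4.3.3 was run with an intensity trend on log2(CPM + 1), with all 5 libraries and 3 groups in one fit, no covariates, 2-sided tests and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. The fit had 2 residual degrees of freedom and a prior of 360.2, so the spread given to a gene came almost wholly from the trend over all genes. With 1 control library no spread among controls could be measured, and that library was assumed to vary as the treated ones did. The labels do not say whether libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

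A second scaling by median-of-ratios size factors, from 11512 genes above 0.05 CPM in every library, is given beside the values as deposited because it changed most calls against the control. Its size factors were 0.317 for the control, 1.42 and 1.31 for forskolin, and 1.65 and 1.12 for cAMP, and its fit had a prior of 15.7 degrees of freedom. GC content and length came from the longest listed transcript of each gene in GENCODE M21, available for 99.1% of tested genes, and were removed from each library with a lowess curve of span 0.3.

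Gene lists numbered 28, and those with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 100 tests. With an estimated correlation camera rests on the fit's 2 residual degrees of freedom, so hardly any list could pass. A failure in that setting therefore does not show that a list was unchanged. The estimates ran from -0.08 (adipocyte) to 0.81 (oxidative phosphorylation). Where an estimate lay above the preset, the preset p-value may overstate the evidence. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined. That rule took, per comparison, genes with a mean at or above 8.84 CPM, the median of tested genes, and without predicted or clone names. It named the 8 largest rises and 8 largest falls past the threshold whose libraries did not overlap, filled where fewer passed by the smallest p in that direction. It added up to 4 members of each described list with the smallest p, and Creb1, Crem, Lgr5, Cd34, Krt15, Lef1, Shh, Gli1, Axin2, Mki67 and Ldha. The text uses a part of the genes so named and of the lists, and that part was chosen after their values were seen.

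The fit was tested on simulated data with 13764 genes and 200 changed genes in each of 10 simulations per comparison. For forskolin against control it recovered 2.2% of 2-fold, 37.6% of 4-fold and 88.8% of 8-fold changes. For forskolin against cAMP it recovered 6.2%, 65.2% and 98.8%. False calls made up 4.2% and 4.7% of calls in these comparisons. Every simulated library, the control included, was drawn with the fitted spread and with no missing genes or shift in scale. These rates therefore do not measure the error of calls against the actual control. Alternatives covered the pseudocount, the filter on low values, the scaling, robust empirical Bayes, the groups in the fit, each treated library left out in turn, the replicate number as a block, the list test, and a minimum fold change. Figures were drawn with matplotlib 3.10.9.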

Results

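Forskolin, an activator of adenylyl cyclase, or cAMP itself was applied to shaved back skin in a lotion, 3 times over 5 days, and the total epidermis was profiled by RNA-seq. The series asks which genes downstream of the transcription factor Creb could speed up the hair cycle. There were 2 libraries with forskolin (10 µM), 2 with cAMP (1.325 mM) and 1 labelled untreated, called the control. The labels do not say whether the control received the lotion, so every comparison with it also holds any effect of lotion and handling. Estimated depths ran from 34200000 to 51700000 reads.

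The control library differed in make-up from every treated library. Mitochondrial genes took 69.3% of its listed values, against 50.7% and 45.6% with forskolin and 43.1% and 58.0% with cAMP. Nuclear genes other than pseudogenes and rRNA took 7.9% in the control and 31.4%, 34.8%, 38.0% and 25.9% in the treated libraries. At 1 CPM or more, 9791 genes were listed in the control and 12867 to 13551 in the treated libraries. Forskolin 2 stood apart in Rn18s-rs5, an rRNA gene, at 55450.5 CPM against 239.7 to 1645.0 CPM elsewhere. Many mitochondrial transcripts have nuclear pseudogene copies, and values of either are uncertain where reads were split between them.

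**Figure D1:**
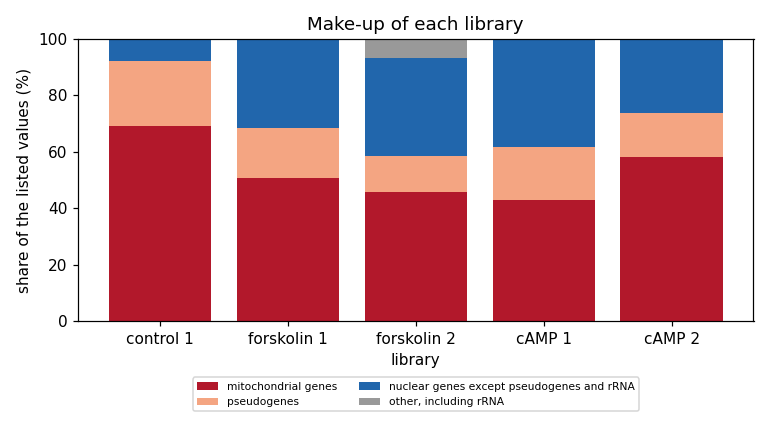
Stacked bars give the share of each library's listed values (%) in mitochondrial genes, pseudogenes, nuclear genes except pseudogenes and rRNA, and the remainder, which includes rRNA. Nuclear genes take 7.9% in the control library and 25.9% to 38.0% in the 4 treated libraries.

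Forskolin against control asks how epidermal transcripts differed between skin given an adenylyl cyclase activator and the library labelled untreated. Of 24 tested CREB and cAMP target genes, 21 rose and none fell as deposited, 21 rose adjusted over the list alone, and 11 rose with median-of-ratios scaling. Per1, a clock gene with CREB sites, stood at 109 ± 0.471 CPM with forskolin (SD, n = 2) and 2.21 in the control, and Fosb, an immediate-early gene, at 40.6 ± 27.5 and 0.425. Heat shock and dissociation stress genes, which respond to tissue handling and include Fosb, rose in the same comparison in 19 of 22 cases, and in 8 with 2 falls with median-of-ratios scaling. limma's camera called that list higher (adjusted p = 0.000257; adjusted p = 0.851 with an estimated correlation), but not with median-of-ratios scaling (0.0781), GC and length correction (0.195) or scaling to nuclear reads (0.115). Of 36 cell cycle genes 34 rose, and 10 with median-of-ratios scaling, among them Mki67, a marker of proliferating cells, at 97.6 ± 1.51 against 5.53 CPM. Of 35 cornified layer genes 11 rose and 7 fell as deposited, with a median log2 change of 0.15, and 5 rose and 21 fell with median-of-ratios scaling, with a median of -1.80.

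In this comparison limma called 9177 of 13764 genes, 9130 higher and 47 lower (99.5% higher). The median gene was 1.69 log2 units higher with forskolin, in libraries whose nuclear share was 31.4% and 34.8% against 7.9% in the control. With median-of-ratios scaling, the median moved to 0.18 and 2997 genes passed, 1980 higher and 1017 lower (66.1% higher). Without forskolin 1, 5342 genes passed. The p-values measure spread between these libraries, which may be technical, and the control has no replicate.

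The largest rises with forskolin were Lcn2, Pcx, Erdr1, Zfp598, Cd163l1, Sprr2a2, Celsr2 and Abca7. Lcn2, an antimicrobial iron-binding protein gene (ENSMUSG00000026822, chromosome 2, 32384633 to 32387797), was at 48.2 ± 15.1 CPM and listed under 1 read in the control (limma adjusted p = 4.06e-16). Against a floor of 3 reads it was at least 793-fold higher as deposited and at least 186-fold higher with median-of-ratios scaling. Such bounds cover counting error only, and the control listed under 1 read 8.2% of the genes expected there at 20 reads or more, against at most 1.97% in a treated library. Erdr1, Cd163l1 and Abca7, also under 1 read in the control, were at 39.9 ± 12.6, 43.3 ± 30.2 and 35.2 ± 3.22 CPM. Pcx, the gene of pyruvate carboxylase, rose by 5.37 ± 0.58 log2 units (SE; limma adjusted p = 5.64e-15), and by 4.71 with median-of-ratios scaling. The stress and barrier alarm list, with 13 of 19 members higher and none lower as deposited and 5 higher and none lower with median-of-ratios scaling, included Stfa3 at 64.0 ± 6.21 CPM against 1.82 and S100a8, an alarmin, at 15.7 ± 1.21 CPM against under 1 read.

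The largest falls with forskolin were Lce1m, Rpl17-ps9, mt-Nd3, Dcn, Lor and Serpinb7, among named genes whose libraries did not overlap. With no filter on low values, limma did not call Rpl17-ps9 (adjusted p = 0.346), mt-Nd3 (0.161), Dcn (0.101), Lor (0.245) or Serpinb7 (0.295). Serpinb7 also did not pass with a pseudocount of 0.1 (0.0694) or 5 (0.0501), nor Rpl17-ps9 with robust empirical Bayes (0.529). Lce1m, a late cornified envelope gene (ENSMUSG00000027912, chromosome 3, 93017810 to 93019060), was at 1.56 ± 1.2 CPM against 39.7 in the control (log2 change -4.08 ± 0.63, limma adjusted p = 2.41e-08). Lor, the gene of loricrin, was at 9.88 ± 0.716 against 27.9 CPM (limma adjusted p = 0.0274), and did not pass with a pseudocount of 0.1 (limma adjusted p = 0.0549). Dcn, a dermal fibroblast gene, was at 4.88 ± 0.841 against 16.3 CPM. Rpl17-ps9, a ribosomal pseudogene, is uncertain because it can share reads with its parent. Col1a2 and Col3a1 passed the threshold, but forskolin 2 lay above the control at 53.3 and 42.7 CPM while forskolin 1 was at 0.968 and 1.26 CPM. Without forskolin 1 their log2 changes were 0.03 and 0.28.

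By list, limma's camera called CREB and cAMP targets (adjusted p = 0.000759), cell cycle (0.000826), stress and barrier alarm (0.0226) and sebaceous gland (0.00117) higher than other genes. It called cornified layer (3.88e-12), dermal fibroblast (2.42e-09) and skeletal muscle genes (0.000453) lower than other genes. As deposited, none of 18 skeletal muscle genes was called singly, with a median log2 change of 0.77. Of 16 fibroblast genes 3 rose and 3 fell, with a median of -0.24. Markers of other cell types and of RNA quality moved in the same libraries: T cell and NK cell (0.0108) and Langerhans cell and MHC class II markers (0.0489) were called higher and mitochondrially encoded genes lower (7.11e-14). Cholesterol synthesis (0.00902) and oxidative phosphorylation genes (0.0491) were called higher as well. With an estimated correlation none of these held, at an adjusted p from 0.851 to 0.901.

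Other settings ended several of these list calls. The CREB list had an adjusted p of 0.0905 with no filter, 0.0609 with GC and length correction, 0.113 without cAMP 1 and 0.124 without cAMP 2. The sebaceous list had 0.153 with a filter of at least 10 and 0.0569 without forskolin 2, and the skeletal muscle list 0.571 with no filter. The stress and barrier alarm list had 0.144 with a pseudocount of 0.1, 0.398 with no filter, and 0.0591, 0.212 and 0.178 without forskolin 1, cAMP 1 and cAMP 2. Median-of-ratios scaling ended the T cell (0.175), Langerhans (0.212), cholesterol (0.582) and oxidative phosphorylation calls (0.929), and over all settings that ended them the adjusted p ran from 0.0502 to 0.228, 0.0674 to 0.634, 0.058 to 0.713 and 0.115 to 0.929. Among these were the fits without forskolin 1 for all but the cholesterol list, without forskolin 2 for the cholesterol and oxidative phosphorylation lists, without cAMP 1 for the Langerhans list, and without cAMP 2 for the T cell and Langerhans lists. The mitochondrial list did not pass with quantile normalization (0.73).

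Creb1 itself was at 23.5 ± 6.24 CPM with forskolin against 1.58 (log2 change 3.22 ± 0.58, limma adjusted p = 1.06e-06; 1.58 with median-of-ratios scaling, limma adjusted p = 0.0121). Of 22 bulge stem cell markers 11 rose and none fell as deposited, and 2 rose and 3 fell with median-of-ratios scaling. The markers fixed by name did not pass as deposited: Lgr5 was at 1.37 ± 1.21 against 0.685 CPM, Cd34 at 5.48 ± 1.4 against 3.64 and Krt15 at 655 ± 204 against 261. With median-of-ratios scaling these turned to -0.72, -1.33 and -0.82, and Cd34 passed as lower (limma adjusted p = 0.0438). Cd34 did not pass with quantile normalization (0.0526), scaling to nuclear reads (0.0585), or GC and length correction on top of median-of-ratios scaling (0.07). With that correction Krt15 and Gli1 passed as lower (limma adjusted p = 0.0368 and 0.0364), whereas as deposited Krt15 passed as higher without cAMP 1 (0.0324) or cAMP 2 (0.0329). Axin2, a Wnt target, rose by 2 log2 units and was at 0.13 after that scaling, and Crem and Ldha rose as deposited and turned to -0.33 and -0.30. Gli1 was at 1.59 ± 2.15 against 1.07 CPM, Lef1 was below the filter, and Shh was not among the genes listed.

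cAMP against control asks the same of the second messenger. Of 24 tested genes of the sebaceous gland, which makes the skin's oil, 21 rose and none fell, 22 rose adjusted over the list alone, and 15 rose and 1 fell with median-of-ratios scaling. Elovl3, a fatty acid elongase, was at 358 ± 104 CPM with cAMP (SD, n = 2) against 6.74 in the control, and Soat1, which esterifies cholesterol, at 381 ± 73.1 against 7.72. Of 20 cholesterol synthesis genes 18 rose, and 12 rose and 1 fell with that scaling, among them Lss, the gene of lanosterol synthase, at 162 ± 5.07 against 4.58 CPM. Nuclear-encoded oxidative phosphorylation genes rose in 35 of 36 cases, and in 13 with that scaling. Cornified layer genes fell in 6 of 35 cases and rose in 4, and in 24 and 2 with that scaling.

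limma called 9025 genes with cAMP, 8965 higher and 60 lower (99.3% higher), with the median gene 1.66 log2 units higher. With median-of-ratios scaling the median was 0.16 and 3113 genes passed, 2042 higher and 1071 lower (65.6% higher).

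The largest rises with cAMP were Lcn2, Pcx, Lpl, Cyp2g1, Acoxl, Fabp5, Pparg and Pdss1. Pparg, a master regulator of lipid cells (ENSMUSG00000000440, chromosome 6, 115361221 to 115490401), was at 48.0 ± 9.96 CPM and under 1 read in the control (limma adjusted p = 5.05e-17). It was at least 790-fold higher as deposited and at least 183-fold higher with median-of-ratios scaling, bounds that cover counting error only, in a control library that listed under 1 read 8.2% of the genes expected at 20 reads or more. Cyp2g1 and Lcn2, also under 1 read in the control, were at 58.2 ± 14.2 and 89.1 ± 39.9 CPM. Lpl, the gene of lipoprotein lipase, rose by 6.00 ± 0.58 log2 units and Fabp5 by 5.72 ± 0.59, and by 4.25 and 3.79 with median-of-ratios scaling. Falls were led by Lce1m, at 1.21 ± 1.71 against 39.7 CPM, Serpinb7, Lor, Kctd12 and Mettl7a1. With no filter on low values, limma did not call Serpinb7 (adjusted p = 0.0962), Lor (0.122), Kctd12 (0.226) or Mettl7a1 (0.241). Kctd12 (0.054) and Mettl7a1 (0.0511) also did not pass with a pseudocount of 0.1, nor Mettl7a1 with a pseudocount of 5 (0.0924). Rpl17-ps9 passed (limma adjusted p = 0.0479), but cAMP 1 lay above the control, at 71.6 against 44.3 CPM, and without cAMP 2 its log2 change was 0.68.

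By list, limma's camera called sebaceous gland (adjusted p = 7.55e-14), cholesterol synthesis (1.31e-08), oxidative phosphorylation (5.12e-08) and cell cycle genes (0.000699) higher than other genes, and cornified layer (2.82e-18), dermal fibroblast (0.00806) and skeletal muscle genes (0.00415) lower. It also called mitochondrially encoded genes, a sign of RNA quality, lower (3.47e-12; 0.771 with quantile normalization), and heat shock and dissociation stress genes higher (0.000159), with 20 of 22 rising as deposited, and 9 rising and 2 falling with median-of-ratios scaling. With an estimated correlation each had an adjusted p of 0.851. The dermal fibroblast call was lost without cAMP 1 (0.189), with no filter (0.398), quantile normalization (0.056), GC and length correction (0.127) and scaling to nuclear reads (0.0522). The skeletal muscle call was lost without cAMP 1 (0.559) and with no filter (0.957), and the heat shock call with GC and length correction (0.142) and scaling to nuclear reads (0.073). The sebaceous list's median log2 change as deposited was 3.83, or 4.22 with the 4 members under the control's floor at their bound. The fibroblast and skeletal muscle lists, called lower than other genes, had medians of 0.84 and 0.81 as deposited. Of their members 6 of 16 and 1 of 18 rose and none fell.

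Of the CREB and cAMP targets, 13 of 24 rose with cAMP and none fell as deposited, and 8 rose and 1 fell with median-of-ratios scaling, or 10 and 5 adjusted over the list alone. The list did not pass (camera adjusted p = 0.234). Those that rose included Egr1, which is also on the heat shock and dissociation stress list, at 120 ± 38.1 against 4.41 CPM, Per1 at 54.7 ± 21.8 against 2.21, Cebpb and Dusp4. Creb1 was at 15.5 ± 1.82 CPM (log2 change 2.68 ± 0.58, limma adjusted p = 3.8e-05), and did not pass with median-of-ratios scaling (1.05, limma adjusted p = 0.0726), quantile normalization (0.95, 0.136) or scaling to nuclear reads (1.23, 0.054). With GC and length correction on top of median-of-ratios scaling Creb1 passed (1.46, limma adjusted p = 0.00936). Mki67 rose to 80.6 ± 15.9 CPM. Crem, Lgr5, Krt15 and Gli1 did not pass as deposited, at 2.59 ± 1.82, 3.45 ± 0.0426, 661 ± 413 and 3.23 ± 0.316 CPM, and Krt15 passed as lower with GC and length correction (-1.38, limma adjusted p = 0.018) and as higher without cAMP 2 (1.86, limma adjusted p = 0.0106). Cd34 and Axin2 passed as higher and turned to -0.49 and -0.32 with median-of-ratios scaling, and Ldha rose by 2.10 and was at 0.03 there.

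Both treatments together against control gave 9814 calls, 9751 higher and 63 lower (99.4% higher), and 3650 with median-of-ratios scaling, 2371 higher and 1279 lower (65% higher). The median gene was 1.67 log2 units higher, and 0.17 with that scaling. The named rises were Lcn2, Pcx, Erdr1, Fabp5, Lpl, Zfp598, Abca1 and Igfbp2. Abca1, a cholesterol exporter, rose by 5.02 ± 0.53 log2 units (limma adjusted p = 3.74e-16), and Igfbp2 by 5.01 ± 0.53. The named falls were Lce1m, Serpinb7, Lor and mt-Nd3. All 12 of these genes passed in the same direction with median-of-ratios scaling. With a filter of at least 10, 11 remained past the threshold, and with no filter 9 did. The falls of Serpinb7 (limma adjusted p = 0.129), Lor (0.135) and mt-Nd3 (0.164) did not pass with no filter.

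Fold changes of forskolin and cAMP went together across genes, with a Pearson r of 0.85 and a Spearman rho of 0.84; genes are not independent replicates. Both used the same control library. Simulated unchanged groups, in which the control was given the same gene means and spread as the treated libraries, gave r = 0.67 from that alone. The covariance was 0.83 against 0.25 simulated. Shared calls numbered 7999 higher and 28 lower, where independent lists of those lengths would share 5946.7 and 0.2, and simulated unchanged groups shared 0. With median-of-ratios scaling r was 0.90 against 0.67 simulated and the covariance 1.19 against 0.15. Shared calls were then 1469 higher and 678 lower, where independent lists would share 293.7 and 79.1 and simulated groups shared 0.7 in all. The control could not be split, and its own make-up and missing genes were not simulated. Part or all of the excess may therefore come from the shared control.

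Forskolin against cAMP asks whether the activator and the messenger acted alike, and it does not use the control's level. Of 24 sebaceous genes 1 was called lower with forskolin over all genes, 15 adjusted over the list alone and 3 with median-of-ratios scaling, and the list's median log2 change was -1.26. The gene called was Elovl3, at 93.3 ± 33.8 against 358 ± 104 CPM with cAMP (SD, n = 2 each; log2 change -1.95 ± 0.48, limma adjusted p = 0.0268). Of 20 cholesterol synthesis genes none was called over all genes, 5 were called lower adjusted over the list alone and 1 with median-of-ratios scaling, and the median was -1.03. limma's camera called both lists lower (adjusted p = 2.86e-18 and 3.3e-10), but not with an estimated correlation (adjusted p = 0.851 each), a setting that rests on 2 residual degrees of freedom. The sebaceous list's estimated correlation was 0.36, above the preset 0.01, which also weakens its call. The cholesterol list's was -0.05, under the preset, yet camera's unadjusted p went from 3.3e-11 to 0.0185. Only the adipocyte list was also under the preset (-0.08), and the oxidative phosphorylation and basal keratinocyte lists had 0.81 and 0.47. Of 24 CREB and cAMP target genes 2 were called higher with forskolin and none lower over all genes as deposited, and 3 higher and 1 lower adjusted over the list alone. With median-of-ratios scaling 1 was higher and none lower, or 4 and 2 adjusted over the list alone. The genes called as deposited were Nr4a3, at 27.0 ± 22.6 against 3.27 ± 1.89 CPM (2.51 ± 0.49, limma adjusted p = 0.000617), and Nr4a2, at 9.57 ± 9.38 against 0.704 ± 0.291 (limma adjusted p = 0.0137). Without forskolin 1, Nr4a3 did not pass and Nr4a2 was below the filter. The heat shock and dissociation stress list did not pass in this comparison (camera adjusted p = 0.571).

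limma called 52 genes, 26 higher and 26 lower with forskolin, with 937 at an unadjusted p under 0.05. With median-of-ratios scaling 48 passed, 13 higher and 35 lower (27.1% higher against 50% as deposited). Groups did not overlap in 33.6% of genes as deposited and in 41.6% with median-of-ratios scaling, and chance gives 33.3%. Named genes higher with forskolin were Nr4a3, Rptn, Serpinb2, Vps37b, Rfx2 and Malat1, a nuclear long noncoding RNA at 544 ± 441 against 118 ± 1.91 CPM. Itga3, a basal keratinocyte integrin, and Rn18s-rs5 filled the list and did not pass, at 39.3 ± 12.7 against 12.4 ± 7.16 CPM and 28200 ± 38500 against 1580 ± 91.8. Named genes lower with forskolin were Cyp2g1, Tmem45b, Rmrp, Elovl3, Acoxl, Clstn3, Hsd3b6 and Lpl, which was at 57.2 ± 20.4 against 201 ± 7.42 CPM.

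**Figure D2:**
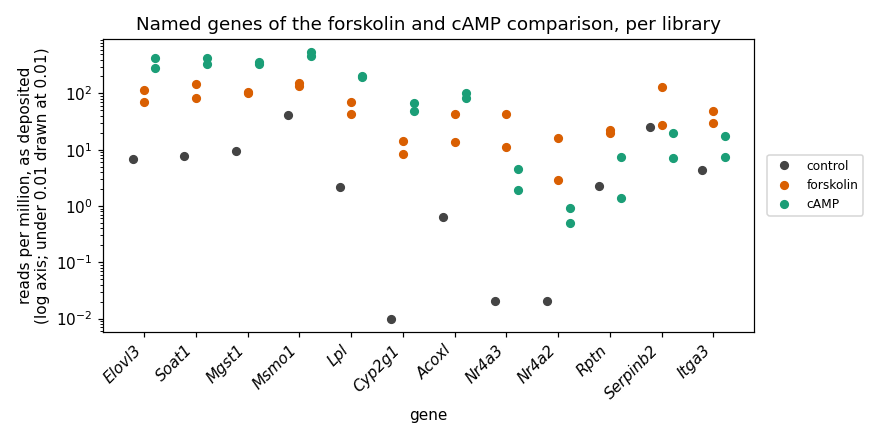
Points give the CPM of named genes in each library on a log axis, for the control, forskolin and cAMP, with values near 0 drawn at the foot of the axis. Elovl3 lies at 69.4 and 117 CPM with forskolin and at 432 and 285 CPM with cAMP, and Nr4a3 at 43.0 and 11.1 against 4.61 and 1.93.

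By list, limma's camera called sebaceous gland (adjusted p = 2.86e-18), oxidative phosphorylation (3.88e-12), cholesterol synthesis (3.3e-10), dermal fibroblast (5.29e-08) and adipocyte genes (0.00195) lower with forskolin, and basal keratinocyte (7.78e-06), cornified layer (3.58e-05), CREB target (0.000205) and T cell genes (0.000879) higher. It also called Langerhans cell and MHC class II (0.0239), stress and barrier alarm (0.00465) and GPCR and cAMP signalling genes (0.00956) higher, and melanocyte genes lower (0.0373). With an estimated correlation each had an adjusted p of 0.851. Msmo1, Soat1 and Mgst1 did not pass over all genes as deposited, at 144 ± 15.3 against 504 ± 50.8, 116 ± 47.3 against 381 ± 73.1 and 106 ± 3.48 against 347 ± 16.2 CPM, and Msmo1 and Mgst1 passed as lower with median-of-ratios scaling (limma adjusted p = 0.0322 each). In the fibroblast list Col1a2 and Col3a1 passed as lower (limma adjusted p = 0.000489 and 0.0181), but the groups overlapped, with forskolin 2 at 53.3 and 42.7 CPM and cAMP 1 at 38.3 and 26.0. Neither passed with median-of-ratios scaling (0.289 and 0.367), and without forskolin 1 their log2 differences were -0.20 and 0.07. The list's adjusted p was 0.734 without forskolin 1 and 0.441 without cAMP 2. That of the CREB list was 0.282 without forskolin 1 and 0.153 with a filter of at least 10, and that of the adipocyte list 0.113 without cAMP 2. That of the Langerhans list was 0.801 without forskolin 1 and 0.613 without cAMP 2, that of the stress and barrier alarm list 0.0572 and 0.53, and that of the signalling list 0.237 without cAMP 1. With no filter these had 0.195, 0.111 and 0.105, with a filter of at least 10 they had 0.116, 0.0571 and 0.0643, and the signalling list had 0.102 with GC and length correction. The melanocyte list turned direction without forskolin 1 (0.511) and was at 0.909 without cAMP 2, and the other settings that ended its call gave 0.0788 to 0.299. Creb1, Crem and Mki67 did not pass, with log2 differences of 0.54 ± 0.47, 1.25 ± 0.50 and 0.29 ± 0.47.

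The calls of single genes in this comparison rested on few libraries. Of the 17 genes named here that passed, 10 remained past the threshold with median-of-ratios scaling, 5 without forskolin 2 or without cAMP 1, and 0 without forskolin 1 or without cAMP 2. With a pseudocount of 0.1 or with GC and length correction 1 remained, and with no filter or with scaling to nuclear reads 0 did. The whole comparison called 27 genes without forskolin 1, 14 without forskolin 2, 71 without cAMP 1 and 10 without cAMP 2.

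**Figure D3:**
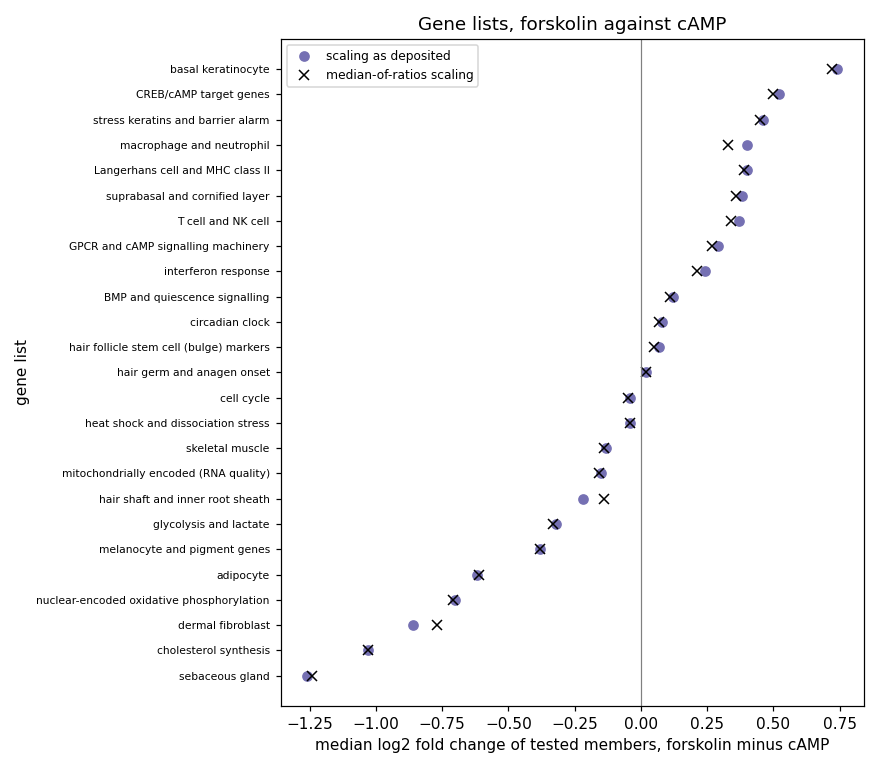
Points give the median log2 fold change (forskolin minus cAMP) of the tested members of each gene list, as deposited and with median-of-ratios scaling. The sebaceous list lies lowest at -1.26 and -1.24, and the basal keratinocyte list highest at 0.74 and 0.72.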

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

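Hspa9-ps1, a pseudogene of a mitochondrial heat shock gene on chromosome X (60576946 to 60578878), had no gene identifier and was in no comparison. It was flagged because every treated library lay above the control: 3.27 and 2.24 CPM with forskolin and 3.85 and 0.924 CPM with cAMP, a mean of 2.57, against 0.0647 in the control. Its reads can be shared with Hspa9, and 9751 of the 13764 tested genes were called higher in the treated libraries as deposited, or 2371 with median-of-ratios scaling. No biological explanation was tested for it. No group held enough libraries to look for a single library far from the rest of its group.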

How the results depend on the processing

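Alternatives were chosen before the data were examined, except 3 added after the result was seen: the GC and length correction, transcripts tested one by one, and scaling to the nuclear read total. A count model, planned in case whole reads could be recovered, was not run because they were not. The main limits were the single control library, its low nuclear share, and 2 libraries per treatment. Over all alternatives, single genes gave the same call in 1203 cases, a weaker one in 235, a stronger one in 16 and the opposite direction in 56. Lists gave the same call in 403 cases, a weaker one in 99 and the opposite direction in 3, and summaries the same in 65 and a weaker one in 27. A summary count was labelled the same if it stayed within a set fold of the main count, whichever genes made it up. For forskolin against cAMP, 52 genes becoming 35 with quantile normalization was so labelled. So were the 48 with median-of-ratios scaling, of which 29 were among the 52. Asking for at least a 2-fold change moved no count, since every called gene already exceeded it, and so says nothing on stability. Low genes limit all comparisons: 47.2% of transcripts in the control library were at the offset that stands for 0. Forskolin 2 stood apart the other way, at 4.2%, against 23.1% in forskolin 1, 19.7% in cAMP 1 and 29.9% in cAMP 2.

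The counts against the control for forskolin, cAMP and both fell with every rescaling. They were 2997, 3113 and 3650 with median-of-ratios scaling, 1902, 2045 and 2422 with quantile normalization, and 3487, 3795 and 4279 with median-of-ratios scaling plus GC and length correction. They were 3271, 3361 and 3887 with scaling to nuclear reads, and 4060, 4356 and 5715 with transcripts tested one by one, where 27764 transcripts were tested. The share higher for both treatments was 65% with median-of-ratios scaling, 52.9% with quantile normalization, 49.1% with GC and length correction and 76.1% with scaling to nuclear reads. For forskolin against cAMP the 52 genes became 16 with a pseudocount of 0.1, 33 with a filter of at least 10, 21 with GC and length correction, 9 with scaling to nuclear reads, and 0 both without a filter and with transcripts tested one by one. At an unadjusted p under 0.05 these last gave 967 genes and 1500 transcripts. The oxidative phosphorylation list with forskolin against control, relative to the median gene, was at -0.03 both with median-of-ratios scaling and with scaling to nuclear reads. Lists past the threshold fell from 50 to 0 with an estimated correlation. That setting leaves camera 2 residual degrees of freedom, so that hardly any list could pass. It also replaced the preset 0.01 by estimates from -0.08 (adipocyte) to 0.81 (oxidative phosphorylation), and a higher correlation weakens a call by itself. The shares of these in the loss were not separated. fry, which tests each list against no change and not against other genes, called 6. These were the adipocyte and cholesterol lists, as higher, in every comparison with the control. It called none for forskolin against cAMP, where the sebaceous and cholesterol lists had fry adjusted p-values of 0.13 and 0.0652. The cause of these changes was not tested.

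Log2 changes that turned direction with forskolin against control were, with median-of-ratios scaling, Crem -0.33, Lgr5 -0.72, Cd34 -1.33, Krt15 -0.82, Gli1 -1.23 and Ldha -0.30. With quantile normalization they were Crem -0.45, Lgr5 -0.98, Cd34 -1.38, Gli1 -1.35 and Ldha -0.03. With GC and length correction they were Crem -0.16, Lgr5 -0.83, Cd34 -1.26, Krt15 -1.15, Axin2 -0.40, Gli1 -1.99 and Ldha -0.44, and there Krt15 and Gli1 passed as lower (limma adjusted p = 0.0368 and 0.0364). With scaling to nuclear reads they were Crem -0.29, Lgr5 -1.08, Cd34 -1.37, Krt15 -0.69, Gli1 -2.05 and Ldha -0.18, and with a pseudocount of 0.1 Gli1 was at -0.70. The cause was not tested.

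With cAMP against control, the log2 changes that turned with median-of-ratios scaling were Crem -1.51, Cd34 -0.49, Krt15 -0.91, Axin2 -0.32 and Gli1 -0.38. With quantile normalization they were Crem -1.60, Lgr5 -0.05, Cd34 -0.52, Krt15 -0.31, Axin2 -0.34 and Gli1 -0.52. With GC and length correction they were Crem -1.43, Cd34 -0.45, Krt15 -1.38, Axin2 -0.73, Gli1 -0.98 and Ldha -0.27, and there Krt15 passed as lower (limma adjusted p = 0.018). With scaling to nuclear reads they were Crem -1.81, Cd34 -0.47, Krt15 -0.85, Axin2 -0.27 and Gli1 -0.41. For forskolin against cAMP, Mki67 was at -0.10 with GC and length correction. The cause was not tested.

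Leaving out each treated library in turn, where a lone library was assumed to vary like the other groups, gave 5342 (without forskolin 1) to 10310 calls for forskolin against control and 7439 to 10173 for cAMP. It gave 7773 to 10823 for both, and 10 (without cAMP 2) to 71 (without cAMP 1) for forskolin against cAMP. The correlation of fold changes ranged from 0.78 to 0.84, and called lists from 37 to 48. With forskolin against control, log2 changes ranged from -4.76 to 0.03 for Col1a2, -4.00 to 0.28 for Col3a1, -0.15 to 0.94 for Lgr5 and -0.96 to 0.99 for Gli1. With cAMP they ranged from -3.30 to 0.68 for Rpl17-ps9 and -0.44 to 0.64 for Crem. For forskolin against cAMP they ranged from -0.60 to 5.13 for Rn18s-rs5 and -4.21 to 0.07 for Col3a1, and the melanocyte list, relative to the median gene, from -0.86 to 0.20.

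No sign of pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.05 across genes, over 2 pairs. With only 2 libraries per treatment, this cannot show that same-numbered libraries shared no batch. With the replicate block, forskolin against cAMP gave 55 genes and 15 lists, against 52 and 13 without it.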

Other observations

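Of the tests weighed here, those on the share of the main cell type and on sebaceous gland cells were chosen only after the result was seen, as was the GC and length correction.

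Glycolysis and clock genes were further groups with most members higher in the treated libraries as deposited. So were most genes: 9130 and 8965 of all 13764 were called higher with forskolin and cAMP, and 1980 and 2042 with median-of-ratios scaling. Glycolysis and lactate genes rose in 20 of 23 cases with forskolin and in 20 with cAMP, and in 2 and 3 with median-of-ratios scaling (limma camera adjusted p = 0.0484 and 0.00341; 0.891 and 0.851 with an estimated correlation). Both calls ended with median-of-ratios scaling (0.582 and 0.12) and with GC and length correction (0.959 and 0.329), and the one for forskolin also without forskolin 1 (0.0863) or forskolin 2 (0.182). Over all settings that ended them the adjusted p ran from 0.0863 to 0.959 and from 0.0699 to 0.329. Slc16a1, a lactate and pyruvate carrier, was at 28.3 ± 2.30 CPM with forskolin and 59.1 ± 3.24 with cAMP (SD, n = 2 each) against 1.5 in the control, and passed under both scalings. Circadian clock genes rose in 14 and 13 of 16 cases, and in 2 and 3 with median-of-ratios scaling, and the list did not pass in either comparison (0.214 and 0.653). Per3, a clock repressor, was at 56.8 ± 4.76 and 42.6 ± 4.53 against 3.71 CPM. Of the heat shock and dissociation stress list, Socs3, an inhibitor of cytokine signalling, was at 32.6 ± 6.20 and 22.7 ± 15.5 against 0.587 CPM.

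Hair follicle lists did not separate the treatments from the control beyond the other genes, except where named here. Bulge stem cell markers rose in 11 and 12 of 22 cases (0.317 and 0.461), hair germ genes in 7 and 6 of 15 (0.0984 and 0.138), and BMP genes in 9 and 11 of 19 (0.429 and 0.288). Hair shaft genes, with 7 tested, rose in 2 cases and 1 case and passed as lower than other genes with forskolin (0.0378; 0.851 with an estimated correlation) and not with cAMP (0.0823). Leaving out any 1 treated library ended that call (0.0542 to 0.0885), as did median-of-ratios scaling (0.538). With that scaling the lists gave 2 and 3, 0 and 1, 1 and 1, and 0 and 0 rises against 3 and 3, 1 and 1, 2 and 3, and 1 and 1 falls. With GC and length correction as well, bulge markers gave 2 rises and 1 rise against 6 and 6 falls. Interferon genes rose in 10 and 6 of 16 cases (0.399 and 0.248), melanocyte genes in 8 and 8 of 15 (0.317 and 0.974), and macrophage and neutrophil genes in 9 and 8 of 17 (0.920 and 0.430). With median-of-ratios scaling these gave 2 and 1, 0 and 2, and 5 and 5 rises against 0 and 1, 0 and 0, and 1 and 0 falls.

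Nearly all genes called against the control were higher in the treated libraries as deposited. With scaling to nuclear reads, the share higher for both treatments went from 99.4% to 76.1%, and the median log2 change from 1.67 to 0.27. That scaling sets the nuclear totals equal in every library, so such a fall would follow whatever the cause. The values show how far the pattern depends on scaling and do not tell its cause. A larger mitochondrial share diluting every nuclear gene alike was argued against as the whole cause, because 8.2% of genes expected at 20 reads or more after median-of-ratios scaling were listed under 1 read in the control. The treated libraries had 0.71%, 0.07%, 0.31% and 1.97%. Few starting molecules in the control library may account for the missing genes: its percentage was 4.2 times that of the highest treated library. A biological change in the treated skin stays open and untested, since the control is 1 library.

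Genes called after median-of-ratios scaling were also weighed. GC content and length were argued against as the whole cause, since 84% of the calls of both treatments kept their direction and threshold after correction, though 79.5% of those higher and 92.4% of those lower did. Putting a treated library in the control's place gave at most 94 calls against 3650, under the bound set beforehand for excluding an unmeasured control spread. That bound was wrong, because 8.2% of expected genes were missing in the control and at most 1.97% in a treated library, so treated libraries cannot stand for the spread of such a control. Whether the calls rest on the control being given the spread of the treated libraries therefore cannot be told apart from an effect of treatment.

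By list medians, sebaceous and cholesterol genes lay higher with cAMP than with forskolin, though 1 of 24 and 0 of 20 passed singly. Neither list passed with an estimated correlation (camera adjusted p = 0.851 each), a setting in which hardly any list could pass. A lower share of the main cell type was argued against by T cell and Langerhans medians of -0.37 and -0.40 beside a sebaceous median of 1.26. The gap was 1.63, with member SDs of 0.34, 0.40 and 0.59. With 1 treated library left out, these 3 medians ranged from 0.15 to 0.57, 0.01 to 0.76 and -1.56 to -0.97 (forskolin minus cAMP, relative to the median gene). Basal keratinocyte and cornified layer medians lay at -0.74 and -0.38, the way such a share would move them. So did fibroblast, adipocyte and melanocyte medians, at -0.86, -0.62 and -0.38 as forskolin minus cAMP, but not macrophage genes, at 0.4. These values do not settle the question. GC and length were argued against as the whole cause, since 95% of the sebaceous median was left after correction. More sebaceous gland cells in the cAMP samples may be the source, and 75% of the 24 members were higher in both cAMP libraries than in both forskolin libraries, between the bounds set. A change of expression within those cells cannot be told apart from it here.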
